A study of Sus scrofa with 6 samples.

How the data were processed

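Small RNA libraries were made from 3 milk and 3 milk exosome samples of Rongchang pigs. Per the labels' protocols, total RNA was extracted with Trizol, about 1 ug entered the TruSeq Small RNA kit, and single-end reads of 36 bp were taken on an Illumina HiSeq instrument. The values are the signal deposited by the authors, a normalized miRNA abundance, and replicates were not pooled. The aligner, the annotation, the method of normalization and any filter are not given in the sources used here. The values are not counts, so a count model was not used, and the settings planned for counts were not run.

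The labelled sheet held 279 lines, of which 34 repeated another line exactly and were dropped. Among the 245 left, 7 sequences carried more than 1 name (14 entries), and each of these names shares its reads with another. Names were matched to the lists without the species prefix and without the suffix that describes a difference from the reference, which gave 221 mature names. A second sheet with 1382 entries has 6 columns of values whose names match no sample label. These 6 columns were not used in any comparison. They were only compared with the labelled columns to find what they hold, and each equalled 1 labelled column on 245 of 245 shared entries, while any other pair of columns was equal on at most 76. Values were called equal within a relative difference of 1e-09. No genome was given, so no coordinates are reported.

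Depth was read from the values. In each library the most frequent value above 0 was taken as 1 read, a rule chosen after the values were seen. Within a tolerance of 0.01 reads, 71.7% to 75.8% of the values in the deep libraries and 77.3% to 87.7% in the shallow ones were whole multiples of it, and at most 39.9% were at double that step. The rest were fractions of a read, so whole reads were not recovered for all entries, and read equivalents are estimates. They cover the listed miRNAs, not the whole library. Libraries were called deep or shallow at 131704 read equivalents, the geometric middle of the range, which gave 2 deep libraries, 1 in each group. Deep and shallow libraries were also tested against each other miRNA by miRNA during exploration. Some miRNAs passed, and this test was left out because the 2 classes were defined from the data and hold both groups. Shares carry exact Clopper-Pearson intervals at 95% on rounded read equivalents, and a value of 0 allows up to 3 reads. Reads without molecular identifiers are not independent molecules, so intervals and floors cover counting error only.

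The main comparison was milk exosome minus milk with limma 3.58.1 in R 4.3.3, with an intensity trend, on log2(value + 1) of entries at 10 or more in at least 3 of the 6 libraries, which kept 141. In shallow libraries a value of 10 is about 1 read or less. In these libraries 1 read is worth 9.01 to 19.7, far above the added 1, so a value listed at 0 there widens the fold change, while in the deep libraries the added 1 shrinks the change of low miRNAs. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The design, the filter, the 20 lists, the rule for named miRNAs and most of the other settings were fixed before the data were examined. The patterns that define the lists were respelled and 1 list was renamed after the data were seen, with the same members matched. Lists with at least 3 tested members, 16 in all, were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests a list on its own and not against other miRNAs. Lists overlap, and the milk immune-related list shares members with most others. Named miRNAs are the 10 with the highest mean over the 6 libraries, the 10 with the smallest p because fewer than 10 passed, and of each tested list the most abundant member and the one with the smallest p, 31 in all.

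Shares of the top 10 miRNAs and numbers of detected sequences were compared by two-sided exact permutation tests, and relations with GC content and length by 100000 permutations, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The other settings fixed beforehand were a replicate block, 3 other scalings, no trend, 2 filters, 2 pseudocounts, names collapsed to the mature name, pig names only and each library left out. Added after the data were seen were the shallow libraries alone, depth class as a term, 1 entry per sequence, a rescaling without the erythrocyte list, list tests under the filters and pseudocounts, camera with an estimated correlation under each setting, and detection after thinning to 1901 reads.

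The fit was tested on simulated data, 50 simulations of 141 miRNAs for this comparison. At the real residual SD it called 3.86% of log2 changes of 4, 0.471% of changes of 2 and 0.151% of changes of 1, with 0.139% of unchanged miRNAs called. At a 10 times smaller SD it called 100%, 99.3% and 85.1%, with 1.80% of unchanged miRNAs called. At this smaller SD, a shift of the muscle list by 3 was called by camera in 50 of 50 simulations, in which miRNAs were drawn without correlation. There were 0 calls among the other lists counted, which left out the GGAG, CCCU, UGCA and 3p arm lists. The list test was not simulated at the real SD.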

Results

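Small RNA was sequenced from 6 samples of Rongchang pigs, 3 of milk and 3 of exosomes collected from milk. Exosomes are small membrane vesicles that cells release and that carry miRNAs, short RNAs that repress messenger RNAs. The title of the series sets miRNAs of milk against miRNAs of its exosomes, and this is the 1 comparison of the design. The design text describes 3 individuals as biological replicates, and it does not say whether milk and exosomes of the same number came from the same animal. It also names small intestine of piglets at 31 days of age, which no sample label does, so the material of the libraries is known only from their labels. P-values here therefore measure the spread between these samples. The deposited table listed 245 distinct entries with 238 distinct sequences, all with pig miRNA names, as normalized abundance.

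Depth differed between libraries of one group. The most frequent value above 0 was taken as the value of 1 read, which gave an estimate of the number of reads behind the listed miRNAs of each library. Milk 1 held 9124580 read equivalents and milk exosome 3 held 8020867. The other 4 libraries held 4348 (milk 2), 1901 (milk 3), 9313 (milk exosome 1) and 3910 (milk exosome 2). The deep libraries were 861 to 4800 times as deep as the shallow ones. A single read stood for a value of 0.0759 in milk 1 and 0.0937 in milk exosome 3, and for 9.01 to 19.7 in the shallow libraries. Binomial intervals below are exact Clopper-Pearson intervals at 95% on these read equivalents, and they cover counting error only.

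All shares of a library given here are shares of the signal of its 238 listed sequences. Entries found only in the second sheet, which has 1382, are not part of them. miR-451, a miRNA of the red blood cell lineage, made up 83.0% of this signal in milk 1 and 81.5% in milk exosome 3. It held 4.46% (95% interval 3.87% to 5.12%) in milk 2, 6.95% (5.84% to 8.18%) in milk 3, 0.0429% (0.0117% to 0.110%) in milk exosome 1 and 0.0256% (0.000648% to 0.142%) in milk exosome 2. miR-16 and miR-144, the latter transcribed together with miR-451, followed it in both deep libraries. miR-144 held 2.53% of milk 1 and 3.89% of milk exosome 3. It was listed at 0 in milk exosome 1 and milk exosome 2. There 3 reads would be shares of 0.0322% and 0.0767%, and the upper limits of the exact 95% intervals were 0.0396% and 0.0943%. The 5 erythrocyte miRNAs together held 90.5% and 89.9% of the deep libraries. They held 12.5% of milk 2, 10.6% of milk 3, 4.33% of milk exosome 1 and 2.92% of milk exosome 2. miR-16 alone held 3.73% of milk exosome 1, and miR-486, named after its values were seen, held 2.71% of milk exosome 2.

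The shallow libraries were led by other miRNAs. miR-1 and miR-133a-3p, miRNAs of skeletal and heart muscle, held 36.4% (34.9% to 38.0%) and 13.6% (12.5% to 14.7%) of milk exosome 2. The muscle list held 55.6% of that library, 10.7% of milk 2, 7.82% of milk exosome 1 and 0.658% of milk 3, against 0.00261% and 0.00443% of the deep libraries. Milk 2 was led by miR-23a at 10.1%, milk exosome 1 by miR-27a at 13.1% and miR-23a at 10.9%. Milk 3 was led by miR-21 at 9.79%, miR-148a-3p at 8.10% and miR-100 at 7.63%. The endothelial and stromal list, which holds miR-100, miR-10b and miR-143, took 16.7% of milk 3, 14.1% of milk exosome 2, 8.43% of milk 2 and 2.68% of milk exosome 1, and 0.0813% and 0.0915% of the deep libraries. The epithelial and mammary list took 7.00% of milk exosome 1, 5.52% of milk 2, 1.74% of milk 3 and 0.0512% of milk exosome 2. It took 0.0437% of milk 1 and 0.0410% of milk exosome 3. miR-221-3p, the most abundant member of this list, alone held 5.12% of milk exosome 1 and 2.97% of milk 2. In these 2 libraries most of the list's share thus came from 1 miRNA.

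**Figure D1:**
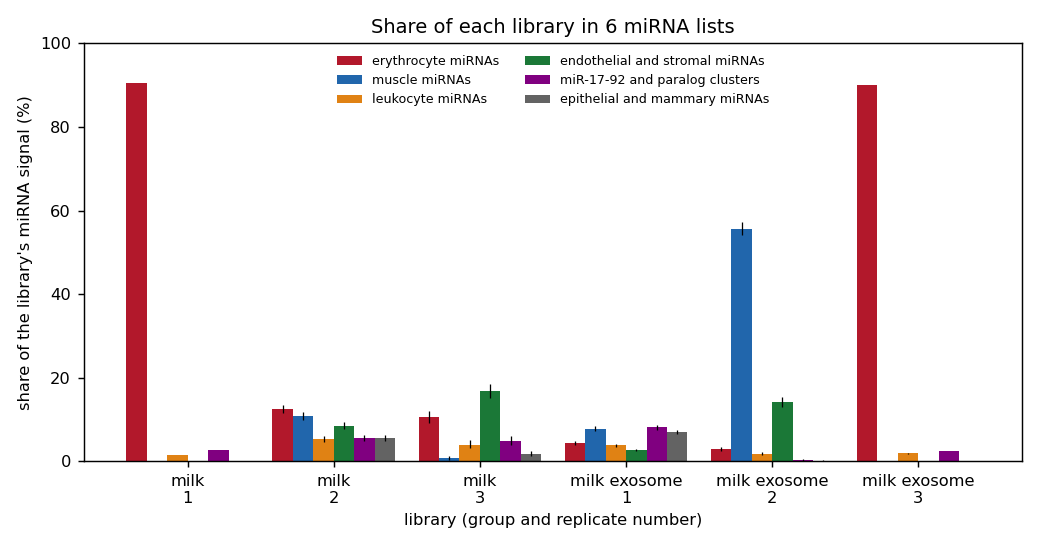
Share of each library's listed miRNA signal (%, vertical axis) in 6 miRNA lists for the 3 milk and 3 milk exosome libraries, with exact 95% counting intervals. The erythrocyte list holds 90.5% of milk 1 and 89.9% of milk exosome 3, and the muscle list holds 55.6% of milk exosome 2.

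The most alike libraries came from different groups. Across miRNAs, which are not independent replicates, milk 1 and milk exosome 3 had a Pearson correlation of log2 values of 0.994, and milk 2 and milk exosome 1 one of 0.768. The highest correlation of milk 1 or milk exosome 3 with a library of its own group was 0.682. The lowest correlation of any pair was 0.348, between milk 1 and milk exosome 2. Milk 1 and milk exosome 3 lay within 2-fold of each other for 106 of the 107 sequences with at least 100 reads in both. Their chi-square per degree of freedom was 595, so they were not 1 library deposited a second time, which at this depth does not tell separate samples from separate preparations of 1 sample. They were kept apart, as the labels have them. The first principal component held 59.9% of the variance and placed both deep libraries apart from the shallow ones. In a second deposited sheet whose column names match no sample label, the values of milk 1 and milk exosome 3 stand under names that share a stem. Milk 2 and milk 3 share another stem, and milk exosome 1 and milk exosome 2 yet another. The stems do not match the 2 groups, and an exchange of labels would not by itself make them match. The group labels, those of milk 1 and milk exosome 3 above all, carry a doubt that extends to the comparisons below.

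**Figure D2:**
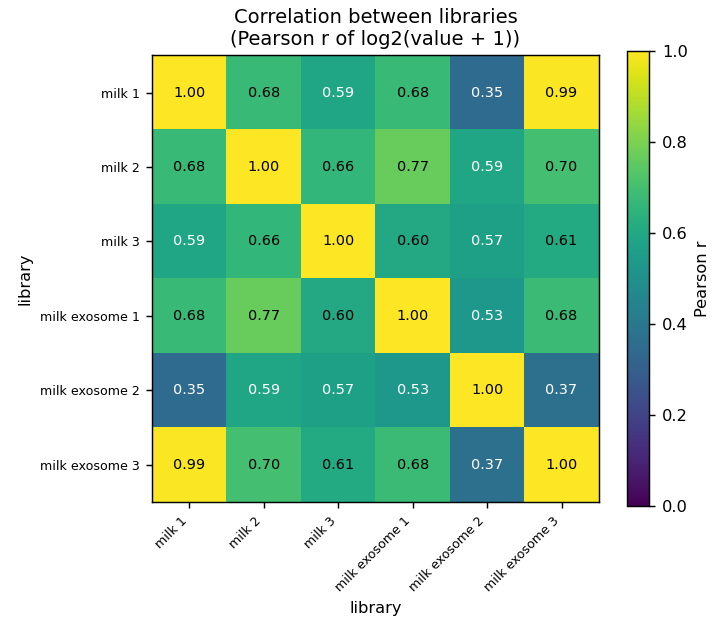
Pearson correlation of log2(value + 1) between each pair of the 6 libraries, with milk and milk exosome libraries on both axes. The highest value off the diagonal, 0.994, joins milk 1 and milk exosome 3.

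In milk exosome against milk, the muscle list lay higher in the exosome group by 1 of 3 list tests, and no single miRNA passed. All 6 tested muscle miRNAs had a positive log2 fold change, with a median of 3.23. miR-1 was at 0.304, 4488 and 69.2 in the 3 milk libraries and at 4242, 27992 and 4.68 in the exosome libraries, a log2 fold change of 3.56 (SE 3.77, n = 3 per group, limma). miR-133a-3p had a log2 fold change of 3.73 (SE 3.71) and miR-133b one of 2.90 (SE 2.52). The muscle list passed limma's camera test with the preset correlation (adjusted p = 0.0329 over 16 lists). The call was lost with adjusted p = 0.760 with an estimated correlation, and fry gave an adjusted p of 0.970. It was also lost without milk 1 (adjusted p = 0.782), without milk exosome 1 (0.0838) and without milk exosome 2 (0.717). It was lost as well with values of 100 or more required (0.0761, median log2 fold change 3.73) and with a pseudocount of 0.1 (0.0549, median 4.11). By camera the list still passed without milk 2 (adjusted p = 1.97e-05, median 5.53), without milk 3 (0.0201, 2.37) and without milk exosome 3 (4.66e-05, 6.17). None of these calls held with an estimated correlation. Without milk 1 or without milk exosome 3, the only deep library left stands in 1 group. Depth class and group cannot be told apart in such a comparison, here and in the results below. Without milk exosome 2 the camera direction was negative and the median log2 fold change of the list was 1.08, against 1.00 for all miRNAs. With 1 library left out in turn, miR-1 ran from 0.64 to 7.20, miR-133a-3p from 1.22 to 7.40 and miR-133b from 1.09 to 5.14. The list also passed in 5 of 9 other splits of the 6 libraries into 3 and 3, each with a smaller adjusted p. In the 4 shallow libraries alone the adjusted p was 0.0131, and 0.920 with an estimated correlation.

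The erythrocyte list had 4 of 5 members lower in exosomes, with a median log2 fold change of -1.07, and it did not pass (camera adjusted p = 0.0833, and adjusted p = 0.760 with an estimated correlation). miR-451 was at 574940, 2782 and 1826 in milk and at 36.0, 19.7 and 612167 in exosomes, a log2 fold change of -4.20 (SE 4.10). miR-144 had one of -4.47 (SE 4.09), which rests on values listed at 0 in 2 exosome libraries. miR-486, named after its values were seen, had the opposite sign at 1.27 (SE 1.57). Among the shallow libraries alone, 2 per group, miR-451 had a log2 fold change of -6.35 (adjusted p = 0.419 in limma). miR-144 was at 129 and 138 in milk and listed at 0 in both exosome libraries, where 3 reads are worth 27.0 and 59.0 (adjusted p = 0.722 in limma). There the erythrocyte list passed (camera adjusted p = 0.00556), and this call too was lost with an estimated correlation (adjusted p = 0.920). Over all libraries it passed by camera without milk 2 (adjusted p = 0.0413) and without milk exosome 3 (0.000235), where the deep class was left in milk alone. It also passed after rescaling to a common total (0.00380, median -2.98), with depth class as a term (0.00791) and with the replicate block (0.0203). It did not without milk 1 (0.846), milk 3 (0.0586), milk exosome 1 (0.753) or milk exosome 2 (0.717), and in the last of these its median was 0.95, against 1.00 for all miRNAs. None of these calls held with an estimated correlation. With 1 library left out in turn miR-451 ran from -9.01 to -1.54 and miR-144 from -9.41 to -1.996. The deep class holds 1 library of each group, in which miR-451 differed by 0.09 on the log2 scale.

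**Figure D3:**
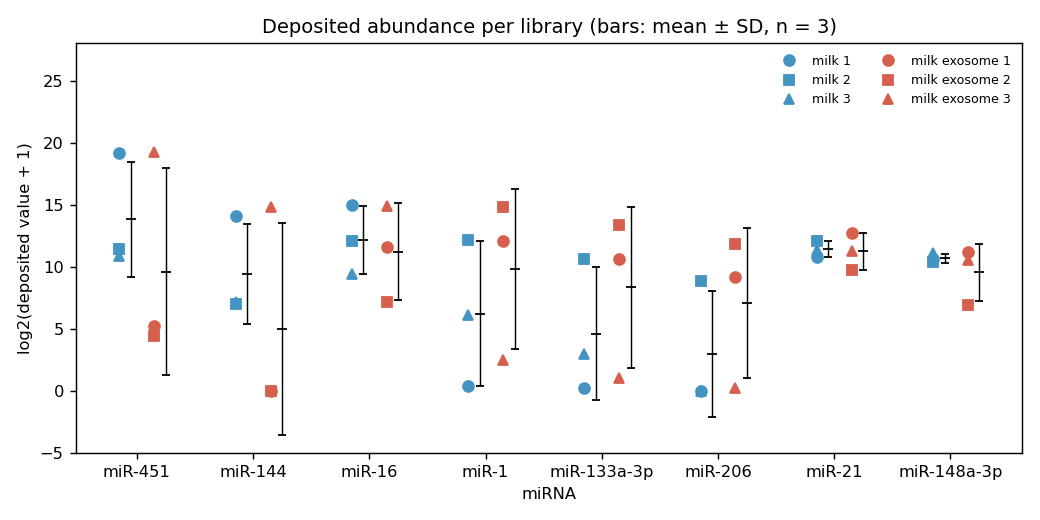
Deposited abundance of 8 miRNAs as log2(value + 1) per library, with points for the 3 milk and 3 milk exosome libraries and bars for the mean ± SD of each group. miR-451 spans 19.7 to 612167 in deposited value within the exosome group.

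Over all miRNAs, 0 of 141 tested passed at an adjusted p of 0.05 in limma, and 0 had an unadjusted p under 0.05, where chance alone gives 7.05. The smallest adjusted p was 0.997. The log2 fold change was positive in 84 and negative in 57, and the median residual SD was 2.50 on the log2 scale. The median log2 fold change of all tested miRNAs was 0.34. It became 0.23 after recentring on the median, 0.04 after recentring on the trimmed mean, -0.31 after rescaling to a common total, with 48 positive and 93 negative, and -0.40 after the same rescaling without the erythrocyte list, with 42 positive and 99 negative. In the shallow libraries alone 0 of 141 passed and 2 had an unadjusted p under 0.05, miR-451 and miR-144. Library totals of the deposited values ran from 26292 in milk 3 to 751401 in milk exosome 3, and overlap was not examined after rescaling. On the deposited values the groups did not overlap for 2 miRNAs, where 10% of miRNAs do so by chance with 3 against 3. These were miR-181a, at 286 ± 9.74 (SD, n = 3) in exosomes and 185 ± 90.7 in milk, and miR-27b-3p, at 201 ± 22.1 and 281 ± 24.8, the latter named after its values were seen.

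The 10 miRNAs with the smallest p, none of which passed, held 9 with higher values in exosomes. miR-361-3p had a log2 fold change of 2.82 (SE 1.64), miR-23b 3.29 (SE 2.08), miR-151-5p 2.44 (SE 1.80), let-7e 2.78 (SE 2.05) and miR-128 2.12 (SE 1.58). miR-99b, miR-10a-5p, miR-139-5p and miR-7134-5p had log2 fold changes of 3.26, 1.91, 2.29 and 2.39. miR-182, a miRNA of epithelial cells, was the exception at -2.46 (SE 1.94). Their unadjusted limma p-values ran from 0.127 to 0.273. With 1 library left out in turn these values kept their signs but moved widely, as for miR-7134-5p (0.55 to 3.63), miR-139-5p (0.68 to 3.13), miR-128 (0.70 to 2.86), miR-151-5p (1.04 to 3.56), miR-23b (1.29 to 4.31), let-7e (1.55 to 4.39), miR-99b (1.63 to 5.41) and miR-182 (-3.59 to -1.25). miR-23b, let-7e, miR-99b, miR-139-5p and miR-7134-5p were listed at 0 in milk 3, the library with the fewest reads. miR-361-3p was listed at 0 in milk 2 and milk 3. It was at 18.0 and 19.7 in milk exosome 1 and milk exosome 2, which is 2 reads and 1 read. Between the deep libraries (milk exosome 3 minus milk 1) several log2 differences went the other way. They were -0.17 for miR-361-3p, -0.46 for miR-23b, -0.26 for miR-151-5p and -0.09 for miR-128. miR-10a-5p and miR-139-5p had -0.23 and -0.08, and miR-182 had 1.31. let-7e, miR-99b and miR-7134-5p kept their direction at 0.17, 0.17 and 0.13.

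Other abundant miRNAs did not pass either. miR-21, common in many cell types, was at 2863 ± 1290 (SD, n = 3) in milk and 3332 ± 3063 in exosomes. miR-148a-3p, an abundant milk miRNA, was at 1665 ± 415 and 1298 ± 1115, with 118 in milk exosome 2. miR-16 had a log2 fold change of -0.92, miR-92a of -0.72, and miR-142-5p, a leukocyte miRNA, of -0.57. miR-23a and miR-27a, transcribed from one cluster, had values of 0.27 and 0.47. After rescaling to a common total they were -0.42 and -0.22, with the median of all miRNAs at -0.31. miR-221-3p was at 4296 in milk exosome 1 and was listed at 0 in milk exosome 2, with a log2 fold change of -1.58 (SE 2.95). miR-10b, an endothelial and stromal miRNA, was at 4993 in milk exosome 2 and 3.95 in milk 1, with a log2 fold change of 2.09 (SE 2.72), which ran from 0.10 to 4.68 with 1 library left out in turn.

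Of the other lists, 0 passed. The let-7 and miR-98 family had 8 of 9 members higher in exosomes and a median log2 fold change 0.24 above that of all miRNAs, and 0.19 above it after rescaling to a common total, where both medians were negative (adjusted p = 0.153 by camera). With 1 library left out this distance ran from -0.42, without milk exosome 2, to 1.35, without milk exosome 1. let-7g, its most abundant member, had a log2 fold change of 0.58, and -0.12 after that rescaling, which moved the median of all miRNAs to -0.31, and 0.12 to 1.07 with 1 library left out. The miR-30 family had 6 of 7 higher (adjusted p = 0.913), with miR-30a-5p at 0.44 and miR-30c-5p at 0.54, and -0.26 and -0.16 after rescaling. With 1 library left out they ran from -0.77 to 1.90 and from 0.18 to 0.89. The sequence listed as miR-30a-5p is also listed as miR-30e-5p, so its identity is uncertain. The miR-148 and miR-152 family had 2 of 3 lower (adjusted p = 0.197). The epithelial and mammary list had 5 of 6 lower (adjusted p = 0.0808), the milk immune-related list 12 of 18 lower (0.0817) and the miR-17-92 list 8 of 10 lower (0.145). In the miR-17-92 list miR-92b-3p, at 2.07 (0.42 to 3.64 with 1 library left out), was 1 of 2 members with a positive value. The leukocyte list had 6 of 11 lower with a median of -0.15 and a mean of 0.19 (adjusted p = 0.913), and the endothelial and stromal list 7 of 14 lower (0.497). Single libraries decided calls by camera at the preset correlation. None of the 15 calls among 96 list tests with 1 library left out held with an estimated correlation (smallest adjusted p = 0.790) or by fry (0.835), although the preset test gave the following adjusted p-values. With milk exosome 2 left out, the endothelial and stromal list lay lower in exosomes (adjusted p = 2.37e-09) and the miR-17-92 list higher (0.0372). The miR-17-92 list lay lower instead without milk 3 (0.0201) and without milk exosome 3 (0.0231). The epithelial and mammary list passed as lower without milk 1 (0.00342) and without milk exosome 1 (0.000919), the endothelial and stromal list without milk 1 (7.42e-05) and the milk immune-related list without milk 2 (0.0492). The let-7 and miR-98 family passed as higher without milk exosome 1 (0.0331).

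The 4 lists by sequence motif and the 2 by arm did not pass either. Members with GGAG were higher in exosomes in 7 of 10 cases (camera adjusted p = 0.440), with CCCU in 19 of 24 (0.142), with GGCU in 11 of 15 (0.913) and with UGCA in 9 of 24 (0.142). miR-339, the most abundant of the GGAG list, had a log2 fold change of 0.40, and -0.29 after rescaling to a common total. miR-1306-3p, of the GGCU list, had one of 1.30. Names of the 5p arm were higher in 23 of 35 (0.497) and those of the 3p arm in 14 of 26 (0.913). No member of any of the 16 lists passed, over all miRNAs or adjusted over the list alone, and 0 members had an unadjusted limma p under 0.05. After rescaling to a common total, which moved the median of all miRNAs to -0.31, the medians of the GGCU, 5p and 3p lists were negative as well, and relative to all miRNAs they kept their signs (0.12, 0.15 and -0.27, against 0.13, 0.10 and -0.23 before). The CCCU list passed as higher without milk exosome 3 (adjusted p = 0.0233, and 0.817 with an estimated correlation). The motif and arm lists overlap with the families.

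A few miRNAs took most of the listed signal of each library in both groups. The 10 most abundant held 67.8% ± 22.7 (SD, n = 3) of milk and 75.0% ± 18.5 of milk exosome, a difference below the spread (two-sided exact permutation p = 0.7, where 3 against 3 cannot go below 0.1). In the shallow libraries alone the values were 54.8% and 65.6%, with n = 2 each. The number of sequences above 0 was 174 ± 45.9 in milk and 182 ± 52.9 in milk exosome (exact permutation p = 1). With each library thinned to 1901 reads it was 106 and 92.5 (exact permutation p = 0.6). In the shallow libraries alone it was 150 and 161.

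Fold change was set against the GC content and length of the 141 sequences, 4 relations in all. The relation with GC content did not pass after adjustment (Pearson r = 0.17, permutation p = 0.0420, adjusted p = 0.0839, and Spearman rho = 0.18, p = 0.0382, adjusted p = 0.0839). In the shallow libraries alone it did, with r = 0.22 and rho = 0.24, and it also did without milk 2 and without milk exosome 3. Length had r = -0.06 and rho = -0.05 (adjusted permutation p = 0.582). These relations are across miRNAs, which are not independent replicates.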

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

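Of the tests in this part, the depth test was set before its result was seen, and the tests on red blood cell RNA, on the labels, on the muscle miRNAs and on other splits of the libraries were chosen after the values they rest on had been seen.

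The columns of the sheet without sample labels were looked at because they hold values outside the comparisons. On the 245 shared entries they added none, since each of the 6 equalled a labelled library on 245 of 245, within a relative difference of 1e-09. The columns equal to milk 1 and milk exosome 3 have names with one stem, those equal to milk 2 and milk 3 share another, and those equal to milk exosome 1 and milk exosome 2 yet another. The names also have endings that cross the groups. One ending is shared by the columns equal to milk 2, milk exosome 1 and milk exosome 3, and another by those equal to milk 3 and milk exosome 2. What the stems and endings stand for is not given in the sources used here, and no comparison used them.

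Milk 1 and milk exosome 3 resembled each other more than their own groups, with a correlation 0.3118 above the highest that either had with its own group. Depth alone is argued against by draws with every library thinned to 1901 reads. In 100 of 100 draws the deep libraries stayed at least 0.1 further from the shallow ones (0.438 ± 0.0129) than these from each other (0.655 ± 0.00787). Thinning made total reads equal, not the reads outside the erythrocyte list. The thinned deep libraries kept 52.7 and 52.9 sequences, against 95.6 to 134 in the shallow ones, so the gap includes this loss. RNA of red blood cells in both libraries stays open as the cause. The erythrocyte list held 90.5% of milk 1 and 89.9% of milk exosome 3. In deposited values, 4 of its 5 miRNAs were higher in both than in each shallow library, against 48 of all 141 miRNAs. The exception, miR-363, was at 109 in milk 1 and 117 in milk exosome 1, where 1 read is worth 9.01, so it decides little. Deposited totals were 692860 and 751401 in the deep libraries and 26292 to 83879 in the shallow ones, which favours higher values in the deep ones. As shares, miR-451 and miR-144 stayed higher, but miR-16 and miR-486 did not. miR-16 held 4.52% of milk 1 and 4.12% of milk exosome 3, against 6.77% of milk 2. miR-486 held 0.418% and 0.442%, against 0.989% of milk 2 and 2.71% of milk exosome 2. A wrong sample label stays open too and cannot be told apart from red blood cell RNA. The excess of 0.3118 is the pattern itself, and the shared column stem is not explained in the labels. Should a label be wrong, the comparison of milk exosome with milk may not be one of these 2 materials.

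The muscle miRNAs stood in one ratio in the 3 libraries that held most of them. miR-1 was 2.88, 2.66 and 2.68 times miR-133a-3p in milk 2, milk exosome 1 and milk exosome 2. The reads of miR-1, miR-133a-3p and miR-206 did not differ in ratio (chi-square p = 0.775 on read equivalents). A single source predicts this, but muscle RNA present in each sample could give it too. The ratio therefore does not tell muscle RNA in each sample from carry-over between libraries. Carry-over from the deep libraries is argued against, as miR-1 held at most 0.000822% of either. Reads of milk exosome 2 in the other 2 libraries stay possible, with 0 of 28 of its sequences below the level this needs at a one-sided Poisson p under 0.01 and 20 at or above it in both libraries, but the expected reads were few and the 28 include muscle miRNAs, so the test was weak. A higher level in exosomes than in milk was seen in 6 of 9 pairs of libraries and cannot be told apart from single libraries with muscle RNA at 3 per group.

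With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 0 miRNAs and the highest of the others 7, in the split that sets milk 1, milk 3 and milk exosome 3 against the rest. It keeps both deep libraries together, and the other 3 splits that do so gave 0. With 0 in the real split, all 10 of 10 splits give at least as many by construction, so their number says nothing. For lists the real split gave 1, the fewest of all splits, and the others 1 to 4. The muscle list, at an adjusted p of 0.0329 in the real split, passed in 5 of the 9 other splits, each with a smaller adjusted p (lowest 1.78e-07), so its call is not particular to the comparison of exosomes with milk.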

How the results depend on the processing

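The shallow libraries alone, the depth term, 1 entry per sequence, the rescaling without the erythrocyte list, thinning, list tests under filters and pseudocounts, and the estimated correlation under each setting were chosen after the data were seen. In limma 0 miRNAs passed in the main comparison and under all alternatives, with at most 5 at an unadjusted p under 0.05, without milk exosome 3, and a smallest adjusted p of 0.327 to 0.999. Over 15 settings besides left-out libraries, 440 of 454 values of the 31 named miRNAs kept their direction and 14 in 7 miRNAs did not, with 0 passing. Several of these settings cannot change a fold change, so many of these values kept their direction by construction. They are the replicate block, no trend, the other filters, pig names only, the depth term and 1 entry per sequence. Rescaling to a common total gave miR-23a -0.42, miR-27a -0.22, let-7g -0.12, miR-30a-5p -0.26, miR-30c-5p -0.16 and miR-339 -0.29. Without the erythrocyte list this rescaling gave -0.53, -0.33, -0.22, -0.37, -0.27 and -0.40 in this order, and miR-181a -0.033. Trimmed recentring gave miR-23a -0.032. Leaving out 1 library gave ranges across 0 for miR-16 (-2.77 to 1.13), miR-21 (-0.92 to 0.60), miR-23a (-0.99 to 1.40), miR-92a (-1.72 to 0.68), miR-27a (-1.14 to 1.84), miR-142-5p (-2.30 to 1.74), miR-30a-5p (-0.77 to 1.90), miR-148a-3p (-1.98 to 0.17), miR-221-3p (-4.34 to 1.69), miR-339 (-1.01 to 1.88) and miR-1306-3p (-0.068 to 2.06). The cause was not tested, except that each scaling moves all miRNAs of a library by 1 factor.

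The number of lists, 1 in the main comparison, was 2 after rescaling to a common total, 2 after that without the erythrocyte list, 4 without a filter, 0 at values of 100 or more, 0 with a pseudocount of 0.1, 2 with one of 10, 0 with an estimated correlation, 2 in the shallow libraries alone, 2 with the depth term, and 2 to 4 with 1 library left out. Of 320 list tests over these settings and the main comparison 36 passed at the preset correlation, 0 with an estimated one (smallest adjusted p = 0.517) and 0 by fry. By camera at the preset correlation, the milk immune-related list passed as lower after the rescaling without the erythrocyte list (adjusted p = 0.00959). It also passed as lower with a pseudocount of 10 (0.0340). The epithelial and mammary list passed as lower without a filter (0.0281). The stricter filter leaves 72 miRNAs and 3 of the muscle list. Samples with the same replicate number had deviations correlated at -0.25, 0.39 and -0.48. The highest value, 0.85, joined milk 1 and milk exosome 3, the deep libraries. Milk 2 with milk exosome 1 gave 0.38, and milk 3 with milk exosome 2 gave 0.47. As depth class enters these deviations, they cannot show whether equal numbers mark 1 animal. Not every sample correlated best with its own number. With the replicate block 0 miRNAs and 2 lists passed, the muscle and the erythrocyte list (adjusted p = 0.0203). The difference in detected sequences, 7.67, was -3.67 at values of 10 or more, -13.2 after thinning and -13.3 to 37.5 with 1 library left out. That of the top 10 share, 7.12 points, ran from -2.18 to 20.2. The relation with GC content passed in the shallow libraries (r = 0.22, rho = 0.24) and ran from 0.010 to 0.22 (r) and 0.019 to 0.27 (rho) with 1 library left out, passing without milk 2 and without milk exosome 3. Length gave r = 0.0028 at values of 100 or more, and -0.15 to 0.081 (r) and -0.088 to 0.028 (rho) with 1 library left out. Pig names only removed nothing. Where 1 library is left out, 2 remain in its group. Where that library is milk 1 or milk exosome 3, the deep class stays in 1 group only and is mixed with the group difference. Depth limits the shallow libraries, where 3 reads are 0.0322% to 0.158% of a library.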

Other observations

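The list tests without a filter and the values by library below were chosen after the data were seen.

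Lists with fewer than 3 tested members gave values in single libraries. The 3 listed miRNAs of the DLK1-DIO3 cluster, an imprinted locus, held 0.217% (exact 95% interval 0.0884% to 0.403%) of milk exosome 2 and 0.0429% of milk exosome 1, and were listed at 0 in milk 2 and milk 3. The neuronal list of miR-128 and miR-7 ran from 0.0263% of milk 3 to 0.755% of milk exosome 2. The intestine and liver list held 0.0690% (0.0142% to 0.202%) of milk 2, 0.00270% of milk 1 and 0.00317% of milk exosome 3, and was listed at 0 in the other 3 libraries. With no filter on low values camera called the DLK1-DIO3 list higher and the intestine and liver list lower in exosomes (adjusted p = 0.0175 for both at the preset correlation, and neither with an estimated one), on values near those of single reads in the shallow libraries. miR-429, the 1 listed member of the miR-200 family of epithelial cells, held 0.210% of milk 3 and 0.0215% of milk exosome 1.

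miR-885-5p, named after its values were seen, was at 1536 in milk 3 and 786 in milk exosome 2, at 43.0 in milk 2 and 99.1 in milk exosome 1, and was listed at 0 in both deep libraries. miR-100 was at 2006 in milk 3, 1534 in milk 2, 708 in milk exosome 2 and 90.1 in milk exosome 1, and at 1.78 and 2.67 in the deep libraries milk 1 and milk exosome 3.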
